A study of Mus musculus with 19 samples.

How the data were processed

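B16F10 melanoma tumours grown under the skin of male C57BL/6 mice were compared between a control diet and a moderate carbohydrate-restricted diet. The series title gives phytochemical extracts to the restricted diet, while the sample titles call both diets supplemented. RNA was measured on Illumina bead arrays in 7 control and 6 restricted tumours. H3K4me3 was measured by chromatin immunoprecipitation on Agilent 2-colour arrays (ChIP-chip) in 3 control and 3 restricted tumours. Groups and replicate numbers were taken from the sample titles and descriptions, and the column names of the expression table were matched to them.

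Per the labels, the authors made the expression table with GenomeStudio, whose version is not given in the sources used here. Its deposited signal values are raw mean bead intensities per probe, without background subtraction or normalization between arrays. The deposited detection p-values come from the negative control beads of the same array. The table holds probe identifiers without gene names, and no probe annotation was at hand. The expression comparison was therefore made per probe, although a single probe per gene and tests of gene lists had been planned.

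The authors scanned the ChIP-chip arrays and extracted them with Agilent Feature Extraction, version 10.7.3.1 per the file headers and 9.3.2.1 per the labels. Per the file headers, the processed red and green intensities were background subtracted, detrended and linearly dye-normalized within each array. The deposited mean signals and local background medians are raw pixel intensities. The deposited log ratios are log10 of Cy5 over Cy3. Per the file headers, 0/1 flags mark outlier, saturated and well-above-background spots. Cy5 carries the immunoprecipitate and Cy3 a reference, which the labels call genomic DNA of pooled control-diet mice in the sample source and input DNA in the labelling protocol, with B16F10 cells as its tissue. The genome build of the probe positions is not given in the sources used here.

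Expression intensities were background corrected and quantile normalized with neqc in limma 3.58.1 (R 4.3.3), with negative control values inferred from the detection p-values and an offset of 16. Probes with a detection p under 0.05 on at least 6 arrays were tested, 11982 of 25697. For ChIP-chip, log2 of Cy5 over Cy3 processed signals was centred on each array's median. Control spots, outlier spots and 426 probes without a position were left out. Probes starting within 1000 bp of the next formed a region, and regions of at least 3 probes were kept, 13484 of 14602 regions. Their medians were 6 probes and 689 bp. A region took the gene name most frequent among its probes on the array. Of 12323 names, 9000 were current, 2037 were replaced by the current symbol and 1286 were left as given.

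Both diet comparisons used limma's lmFit and eBayes, restricted minus control, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Per-array measures were compared with exact permutation tests. Tools besides limma were statmod (version 1.5.0) and data.table (version 1.17.8). The samples, groups, tests, alternatives and 27 gene lists were fixed before the data were examined. Moving the gene lists from expression to H3K4me3 regions was decided later. Each listed gene took its region with the highest mean ratio over the 6 arrays, so that the choice did not look at diet. Diet differences of the 22 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The H3K4me3 level of a list was set beside 10000 random gene lists of the same size, drawn from 10218 genes in 10 classes of reference signal. Random lists were drawn anew under 10 alternatives, with the regions kept. The level comparison and the reference signal by chromosome were also chosen after the values were seen.

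Expression probes named are the 2 with the largest change in each direction past the threshold. The fixed rule asked for 12 genes in each direction, and the number was lowered because the probes have no gene names. No H3K4me3 region passed, so the 3 regions with the smallest p in each direction are named, as the rule required. List members with a diet difference are among the 4 with the smallest p in their list. Members named for their H3K4me3 level were chosen after their values were seen, from among the highest or lowest of their list or family.

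Alternatives for expression were another background correction or none, array medians in place of quantiles, other filters, mouse number as a block, array weights, limma's trend and each mouse left out. Alternatives for H3K4me3 were normexp with an offset of 50, quantile normalization, the deposited log ratios, a filter on reference signal, a gap of 500 bp, single probes, high regions, medians over probes, slide or mouse number as a block, limma's trend and each mouse left out. The expression arrays' 2 background sets as a block were added after the data were seen. Changes of known size were added to 200 expression probes and 200 H3K4me3 regions in simulated data with the measured spread. Limma recovered 25.4%, 83.6% and 98.5% of expression changes of 0.5, 1 and 2 on the log2 scale, with 9 false calls among 147. It recovered 0%, 8.96% and 56.1% of H3K4me3 changes of the same sizes, with 1 false call among 44. The simulated H3K4me3 data had 858 regions at an unadjusted p under 0.05 and the measured data 373, so these rates are for the simulated data only. The correlations of expression with H3K4me3, the gene lists on expression, means over the probes of a gene and the BeadChip as a block could not be computed, because neither gene names nor BeadChip names come with the expression values.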

Results

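Tumours of B16F10 cells, a melanoma line from C57BL/6 mice, were compared between male mice on a control diet and mice on a moderate carbohydrate-restricted diet. The series title gives phytochemical extracts to the restricted diet, whereas the sample titles call both diets supplemented. RNA was measured in 7 control and 6 restricted tumours. Trimethylated lysine 4 of histone H3 (H3K4me3), a mark of active promoters, was measured in 3 control and 3 restricted tumours. The mice were 5 weeks old and ate their diet for 1 week before the cells were injected. The later feeding time is given as 24 days in the series description and as 2 weeks in the sample protocols. Control tumours had 11689 ± 271 detected expression probes (SD, n = 7) and restricted tumours 12080 ± 347 (SD, n = 6). The difference of 391 probes had an exact permutation p of 0.0437 (two-sided). Restricted tumours 1 and 2, with 11538 and 11858, lay inside the control range of 11343 to 12030, and the other restricted tumours had 12068 to 12457. On the ChIP-chip arrays, 84.7% to 89.9% of probes were well above background in the immunoprecipitate. The number of arrays limits the precision of both assays.

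The expression comparison asked which transcripts differed in the tumours between the diets. Of 11982 probes tested, 2271 changed, 953 to a higher and 1318 to a lower level in restricted tumours. The median size of these changes was 0.69 on the log2 scale. Changes above 2-fold were mostly decreases, with 400 probes lower and 57 higher. The most reduced probe was ILMN_2996479, with a log2 intensity of 7.57 ± 0.16 in control tumours (SD, n = 7) and 5.24 ± 0.96 in restricted tumours (SD, n = 6). Its log2 change was -2.32 (SE 0.33, limma adjusted p = 0.00126). ILMN_1231381 was at 7.56 ± 0.43 in control and 5.26 ± 0.79 in restricted tumours, a log2 change of -2.30 (SE 0.31, limma adjusted p = 0.00098). The most increased probe was ILMN_2882658, at 5.57 ± 0.67 in control and 8.16 ± 2.34 in restricted tumours. Its log2 change was 2.60 (SE 0.81, limma adjusted p = 0.0377). ILMN_2885990 was at 5.69 ± 0.25 in control and 7.85 ± 1.94 in restricted tumours, a log2 change of 2.17 (SE 0.65, limma adjusted p = 0.0320). Restricted tumour 4 had the highest signal of both increased probes, 11.84 for ILMN_2882658 and 11.06 for ILMN_2885990. Without restricted tumour 2 the number of changed probes was 1441, and with array weights it was 3951. With each array centred on its median in place of quantile normalization it was 6055, of which 5079 were higher, and the median log2 change of all tested probes was 0.37 in place of 0.05. ILMN_2882658 missed the threshold without any 1 of control tumours 1, 2, 3, 4, 5 and 7 or restricted tumours 1, 2, 3 and 4 (limma adjusted p = 0.0523 to 0.0761). ILMN_2885990 missed it without any 1 of control tumours 2, 3, 4, 5 and 7 or restricted tumour 3 (limma adjusted p = 0.0516 to 0.0636). Probe identifiers came without gene names, so no gene or pathway is named for these changes.

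The signal of the 10632 probes detected on none of the 13 arrays did not follow diet alone. Their median raw intensity was 149.8 to 162.7 on the 7 control arrays and 159.4 on restricted array 1, but 180.2 to 188.9 on restricted arrays 2 to 6. The diet difference in this background was 25.9 intensity units (exact permutation p = 0.00175, two-sided). The first principal component of the normalized values, 35.7% of the variance, parted the same 8 and 5 arrays. ILMN_2996479 and ILMN_1231381 followed the division by component 1. They were at 7.20 and 6.83 on restricted array 1, and at no more than 4.90 and 5.25 on the other restricted arrays. Compared between these 8 and 5 arrays in place of the diets, 3147 of the 11982 tested probes changed, against 2271 between the diets. The 2 comparisons differ by restricted array 1 alone, so the counts do not separate array set from diet. With the background set as a block, 305 probes changed with diet, 91 of them higher. The log2 differences of ILMN_2996479 and ILMN_1231381 were then -0.37 and -0.73 (limma adjusted p = 0.248 and 0.258). Those of ILMN_2882658 and ILMN_2885990 were 3.97 and 3.26 (limma adjusted p = 0.170 and 0.162). These blocked values rest on restricted array 1, the lone restricted array in the dim set. Compared with the 7 control arrays, that array alone gave 437 changed probes, in a fit that takes its spread from the controls and assumes that the lone array varies as they do.

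**Figure D1:**
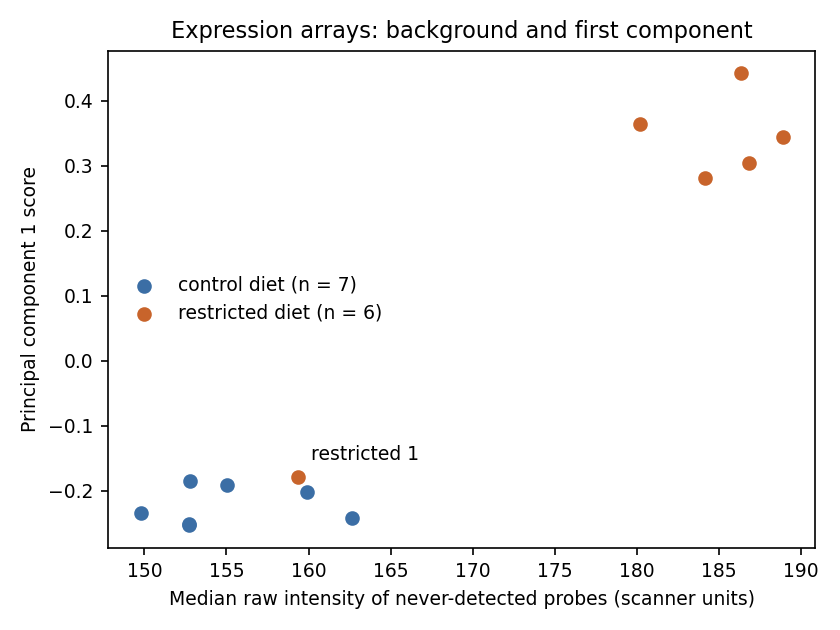
Median raw intensity of never-detected probes (scanner units, x axis) and principal component 1 score (y axis) for each expression array, 7 control and 6 restricted. Restricted array 1, at 159.4, sits with the control arrays (149.8 to 162.7), and the other 5 restricted arrays lie between 180.2 and 188.9.

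H3K4me3 over both diets was high for 6 lists: oxidative phosphorylation and TCA cycle, glycolysis, hypoxia response, cell cycle, ER stress and amino acid response, and H3K4 methylation machinery. The 28 measured oxidative phosphorylation and TCA cycle genes had a median log2 ratio of 0.52, higher than 99.99% of random gene lists matched on reference signal. Ndufb8, a subunit of respiratory complex I, was at 1.45 ± 0.60 (SD over the 6 arrays). The 17 glycolysis genes had a median of 0.36 (percentile 96.7 of their random lists), with Ldha, lactate dehydrogenase A, at 1.04 ± 0.56 and Gapdh at 0.92 ± 0.42. The 20 hypoxia response genes stood at 0.39 (percentile 96.2), with Mxi1 at 1.07 ± 0.53 and Vegfa, the vascular growth factor, at 0.78 ± 0.31. The 25 cell cycle genes stood at 0.34 (percentile 99.7), with the mitotic kinase Plk1 at 1.30 ± 0.53, the mitotic motor Kif11 at 1.29 ± 0.42 and Myc at 1.00 ± 0.25. The 20 ER stress and amino acid response genes stood at 0.37 (percentile 98.3), with the stress transcription factor Xbp1 at 1.38 ± 0.30 and the amino acid transporter chain Slc3a2 at 1.36 ± 0.36. The 17 genes of the H3K4 methylation machinery stood at 0.48 (percentile 99.8), with the demethylases Kdm1a at 1.16 ± 0.62 and Kdm5c at 1.12 ± 0.52. New random lists were drawn under 10 alternatives, 4 of the ratios and 6 without 1 mouse each. The lowest percentile was then 99.7 for oxidative phosphorylation, 97.8 for the cell cycle, 97.6 for the machinery and 91.0 for glycolysis. It was 83.7 for the hypoxia response and 53.6 for the ER stress genes, both with the median over a region's probes. That setting lowered the levels of all 6 lists, to between 0.06 for the ER stress genes and 0.24 for the machinery.

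Other metabolic, stress and immune lists were below percentile 95 of their random lists, although 4 of them passed it under an alternative. The 18 NRF2 and antioxidant genes had a median log2 ratio of 0.30 (percentile 89.8), although Prdx1, a peroxiredoxin, was at 1.37 ± 0.43 and Mt1, a metallothionein, at 1.33 ± 0.90. The 22 fatty acid and sterol synthesis genes stood at 0.30 (percentile 91.9), with Fdps at 1.06 ± 0.71. The 20 apoptosis and p53 target genes stood at 0.26 (percentile 89.6), with Trp53, the gene of p53, at 0.97 ± 1.02. The 17 early response and heat shock genes stood at 0.25 (percentile 89.7), with Nr4a1 at 1.44 ± 0.36 and Fos at 1.05 ± 0.38. The 17 sirtuin, AMPK and autophagy genes stood at 0.24 (percentile 86.2), with Atg7, an autophagy enzyme, at 1.88 ± 0.75. The 25 insulin, IGF and mTOR genes stood at 0.21 (percentile 86.7), with Eif4ebp1 at 1.22 ± 0.31 and Igfbp2 at -0.97. The 18 fatty acid oxidation and ketone use genes stood at 0.08 (percentile 26.3), with Pdk4, an inhibitor of pyruvate entry into the TCA cycle, at -0.99 ± 0.44. The 22 tumour invasion and angiogenesis factors stood at 0.02 (percentile 24.96), with Mmp14, a membrane-bound matrix protease, at 1.24 ± 0.53. The 6 of 28 interferon response genes that were measured stood at 0.09 (percentile 37.4). The 7 of 22 antigen presentation genes measured stood at 0.41 (percentile 94.3). Medians of the antigen presentation genes taken per array were lower, at 0.05 ± 0.23 in control and -0.18 ± 0.40 in restricted tumours (SD, n = 3 each). Without control tumour 2 the antigen presentation genes stood at 0.19 (percentile 73.0). The interferon response genes ranged from -0.09 (percentile 10.1) without restricted tumour 2 to 0.21 (percentile 64.9) without control tumour 2. Without restricted tumour 3 the insulin, IGF and mTOR genes stood at 0.10 (percentile 67.35), and without control tumour 1 the early response genes stood at 0.17 (percentile 73.5). The tumour invasion factors stood at -0.02 without control tumour 3. Without control tumour 2 or restricted tumour 3 the fatty acid oxidation genes stood at 0.05. The filter on reference signal raised the sirtuin genes to 0.39, and the highest value of the early response genes over all alternatives was 0.42. With the median over probes the levels were 0.09 for the NRF2, 0.12 for the fatty acid and sterol synthesis, 0.16 for the apoptosis, 0.12 for the early response, 0.10 for the sirtuin, 0.12 for the insulin and -0.01 for the fatty acid oxidation genes. In that setting the apoptosis genes reached percentile 97.3 and the antigen presentation genes 98.8. The fatty acid and sterol synthesis genes reached 97.7 without control tumour 2, and the early response genes 97.0 with normexp. The deposited log ratios, which are not centred, lowered every list, with the fatty acid oxidation genes at -0.02 and the tumour invasion factors at -0.07.

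Among the cell type markers, 5 macrophage and dendritic cell genes had a median log2 ratio of -0.59, lower than all but 0.16% of their random lists. C1qb, a complement gene of macrophages, was at -2.31 ± 1.00. The 10 endothelial genes stood at -0.20 (percentile 1.19), with the vascular receptors Flt4 at -1.43 ± 0.39 and Kdr at -0.77 ± 0.24. The 5 adipocyte genes stood at -0.29 (percentile 2.78) and the 9 fibroblast, pericyte and matrix genes at -0.15 (percentile 3.70), with Pdgfra at -0.54 ± 0.17. The 6 skeletal muscle genes stood at -0.14 (percentile 6.43). The 5 measured pigment cell genes stood at -0.16 (percentile 8.08), from Trpm1 at -1.28 ± 0.43 to the transcription factor gene Tfap2a at 1.02 ± 0.34. Many members of these lists had no tested region, and the medians cover only those measured. These were 5 of 25 macrophage, 10 of 20 endothelial, 5 of 15 adipocyte, 9 of 26 fibroblast, 6 of 20 skeletal muscle and 5 of 23 pigment cell genes. With normexp the levels moved towards 0, to -0.17 for the macrophage, -0.06 for the endothelial, -0.08 for the adipocyte, -0.01 for the fibroblast and -0.04 for the skeletal muscle genes, and to 0.03 for the pigment cell genes. Without control tumour 2 the endothelial genes stood at -0.12 and the skeletal muscle genes at -0.05. With the median over probes the fibroblast, skeletal muscle and pigment cell genes stood at -0.04, -0.03 and -0.05. Over the same 10 alternatives the highest percentile was 0.33 for the macrophage, 4.93 for the endothelial, 4.08 for the adipocyte, 8.76 for the fibroblast, 19.5 for the skeletal muscle and 14.85 for the pigment cell genes. Lists with fewer than 5 measured genes were not tested. Their medians were -0.47 for 3 T and NK cell markers, -0.62 for the neutrophil marker Mmp9, 0.04 for the B cell marker Pax5, -0.06 for the keratinocyte marker Sfn and 0.28 for the erythroid marker Klf1.

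**Figure D2:**
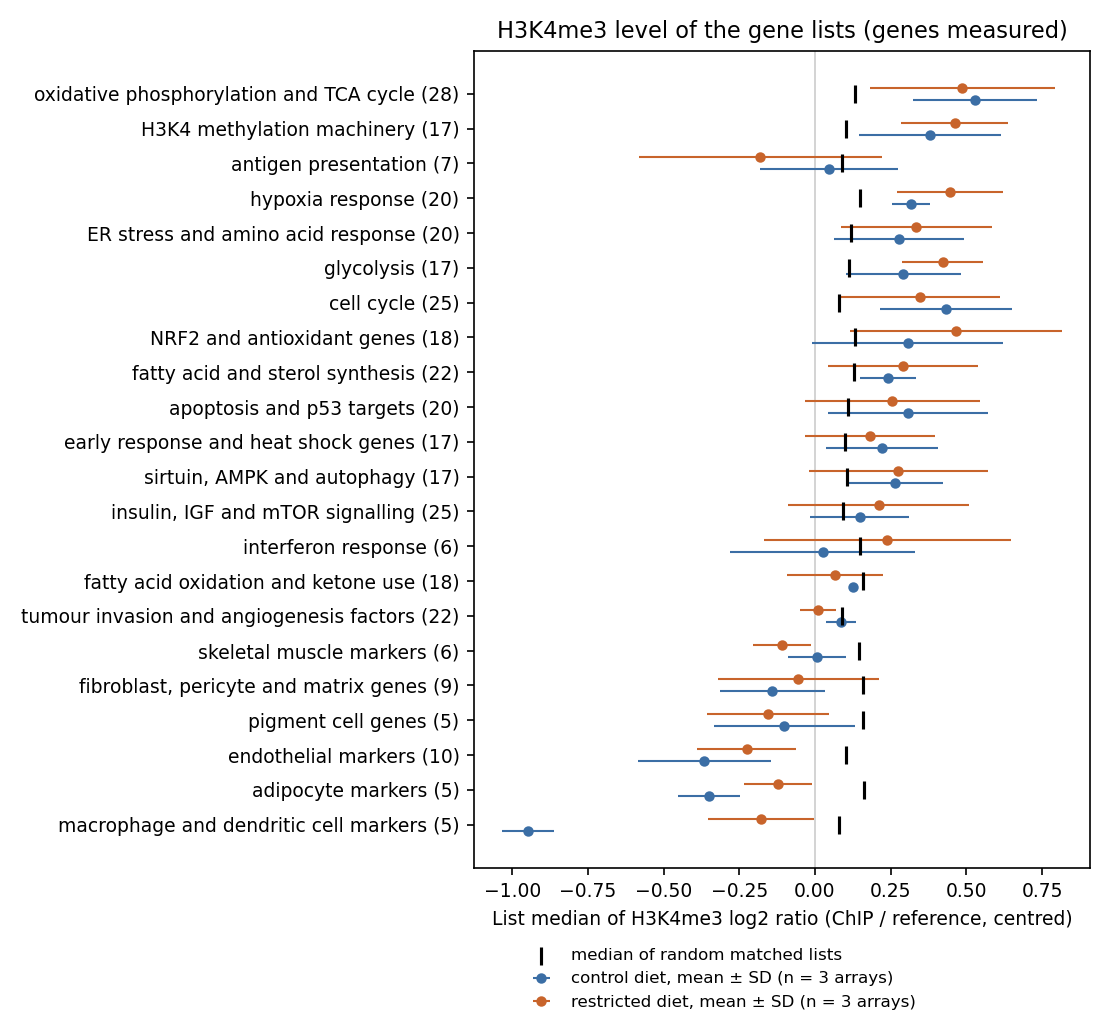
Median H3K4me3 log2 ratio of each gene list (x axis), shown as the mean ± SD of 3 control arrays (blue) and 3 restricted arrays (orange), with the number of genes measured in brackets; lists are ordered by the median of their genes' means over all 6 arrays. Black bars mark the median of random matched lists, and the oxidative phosphorylation and TCA cycle genes, at 0.53 ± 0.21 in control and 0.49 ± 0.30 in restricted tumours, lie above theirs at 0.13.

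The H3K4me3 comparison asked which promoters differed in the mark between the diets. The smallest p for higher H3K4me3 in restricted tumours was at Brms1l, a gene of a histone deacetylase complex subunit (chromosome 12, 56779080 to 56779399). Its log2 ratio was -1.48 ± 0.31 in control and 0.35 ± 0.32 in restricted tumours (SD, n = 3 each), a difference of 1.83 (SE 0.25). The region at Snx11, a sorting nexin gene (chromosome 11, 96593474 to 96593974), differed by 1.19 (SE 0.18). The region at Ranbp2, a nuclear pore gene (chromosome 10, 57893126 to 57893664), differed by 2.24 (SE 0.35). In the other direction, 1 of the regions of Wdr5, a core subunit of H3K4 methyltransferase complexes (chromosome 2, 27362286 to 27362597), was at -0.02 ± 0.53 in control and -1.75 ± 0.31 in restricted tumours, a difference of -1.73 (SE 0.32). The region at Tex9 (chromosome 9, 72290379 to 72290659) differed by -1.52 (SE 0.33). The region at Scarb1, the receptor for high-density lipoprotein (chromosome 5, 125629742 to 125630213), differed by -0.81 (SE 0.19). None of these 6 regions passed the test (limma adjusted p = 1.00 for each). With normexp the differences were 0.91 at Brms1l, 1.09 at Ranbp2, -0.95 at Wdr5 and -1.01 at Tex9, and with the median over probes 0.31 at Snx11. On the slide that held an array of each diet, the differences were 2.33 at Brms1l, 1.12 at Snx11, 1.53 at Ranbp2, -1.76 at Wdr5, -1.97 at Tex9 and -0.89 at Scarb1.

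Over all 13484 regions, limma called 0 changed between the diets. At an unadjusted p under 0.05 there were 373 regions, where 674 would come by chance. With the slide as a random or fixed block there were 677 and 940. Control tumours 1 and 3 shared a slide, restricted tumours 2 and 3 another, and control tumour 2 and restricted tumour 1 the last. The fixed block thus took the diet difference from control tumour 2 and restricted tumour 1 alone. The median 95% interval of a region's difference reached 0.63 to either side on the log2 scale. In simulated data limma recovered 8.96% of differences of 1 and 56.1% of differences of 2. The simulated data, with changes added to 200 regions, had 858 regions at an unadjusted p under 0.05, against 373 in the measured data. The recovery rates are therefore given for the simulated data only, and the power on the measured arrays is not known. A mean log2 ratio of at least 1 was reached by 602 regions in control and 646 in restricted tumours, 347 of them in both. The mean ratios of the groups correlated across regions with r = 0.809, where regions are not independent replicates. The groups' arrays did not overlap at 945 regions, 7.01%, where chance gives 10%.

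Across the gene lists, 0 of 22 passed camera, 0 passed with an estimated correlation and 0 passed fry, and 2 had a camera p under 0.05. None of the 342 list members passed over all regions, and none passed adjusted over the list alone. At an unadjusted p under 0.05 were 14 of the 342 members, beside 373 of all 13484 regions, where 674 regions would come by chance. The macrophage and dendritic cell markers stood at -0.95 ± 0.08 in control and -0.18 ± 0.17 in restricted tumours (SD, n = 3 each), with 4 of 5 genes higher in restricted tumours. The mean difference of the 5 genes was smaller than that of these medians, at 0.44, and it was 0.13 with normexp and 0.20 to 0.67 with 1 mouse left out. Fcgr1, an antibody receptor, differed by 0.81 (SE 0.32) and Cd14, a receptor for bacterial products, by 0.61 (SE 0.28). Camera gave this list an adjusted p of 0.145, and an adjusted p = 0.966 with an estimated correlation. Without control tumour 1 its camera adjusted p was 0.0185, and 0.992 with an estimated correlation. The pigment cell genes had 4 of 5 members lower in restricted tumours, among them Trpm1, a channel gene of melanocytes, by -0.63 (SE 0.24). Their mean difference was -0.30, and it was -0.16 with the median over probes. With the slide as a fixed block, which rests on control tumour 2 and restricted tumour 1, it was -0.13. Medians of the pigment cell genes taken per array differed less, at -0.10 ± 0.23 in control and -0.15 ± 0.20 in restricted tumours (SD, n = 3 each). Camera gave an adjusted p of 0.0878, and an adjusted p = 0.966 with an estimated correlation. Without control tumour 2 its camera adjusted p was 0.0305, and 0.983 with an estimated correlation. With normexp it was 0.0317, and 0.694 with an estimated correlation.

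The members of other lists with the smallest p went in both directions. Of the 28 oxidative phosphorylation and TCA cycle genes, 18 were higher and 10 lower in restricted tumours. H2-Eb1, a class II antigen presentation gene, differed by 0.89 (SE 0.25), and Erap1, which trims peptides for class I presentation, by -1.07 (SE 0.39). Setd7, a lysine methyltransferase, differed by 0.54 (SE 0.17), with 11 of 17 machinery genes higher in restricted tumours. Pdk4 differed by 0.68 (SE 0.22), with 8 of 18 fatty acid oxidation and ketone use genes higher. Irf1, an interferon response regulator, differed by 0.65 (SE 0.27) and the collagen gene Col5a1 by 0.65 (SE 0.27). Sod2, the mitochondrial superoxide dismutase, differed by 0.44 (SE 0.18), Bax, a cell death gene, by 0.48 (SE 0.19), and Ulk1, an autophagy kinase, by -0.73 (SE 0.30). For the glycolysis genes, 9 were higher and 8 lower in restricted tumours, with Slc16a1, a lactate transporter, at a difference of 0.35 (SE 0.16). For the hypoxia response genes, 13 were higher and 7 lower, and for the cell cycle genes 14 were higher and 11 lower. For the oxidative phosphorylation, cell cycle, NRF2, fibroblast and skeletal muscle lists, the median difference, the mean difference and camera's direction did not share 1 sign. None of the members in this paragraph passed the test.

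The enrichment of H3K4me3 over the arrays was compared between the diets as the 95th percentile of the centred log2 ratio. It was 2.40 ± 0.62 in control and 2.48 ± 0.73 in restricted tumours (SD, n = 3 each). The difference of 0.08 had an exact permutation p of 0.9 (two-sided), where 3 against 3 arrays allow none below 0.1. With the SD of the log2 ratios in its place the direction turned, to a difference of -0.0100 (exact permutation p = 1.00). Correlations between arrays across regions ran from 0.485 to 0.703, with a mean of 0.538 within and 0.558 between diets. The exact permutation p was 0.9, one-sided for a higher correlation within diets. Arrays that shared a slide correlated at a mean of 0.523 and arrays of other slides at 0.556.

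The labels give the Cy3 reference as pooled DNA of control-diet mice but its tissue as B16F10 cells, so whether it came from tumour or host is not settled. It differed by chromosome in the same way on all 6 arrays. Regions on chromosome 6 had a median log2 reference signal of 0.29 ± 0.01 above that of all regions (SD over the 6 arrays, 623 regions). On the X chromosome the median was -0.27 ± 0.04 (372 regions). The other autosomes ranged from -0.09 on chromosome 13 to 0.09 on chromosome 10. In the immunoprecipitate the median of chromosome 6 was 0.30 ± 0.06.

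**Figure D3:**
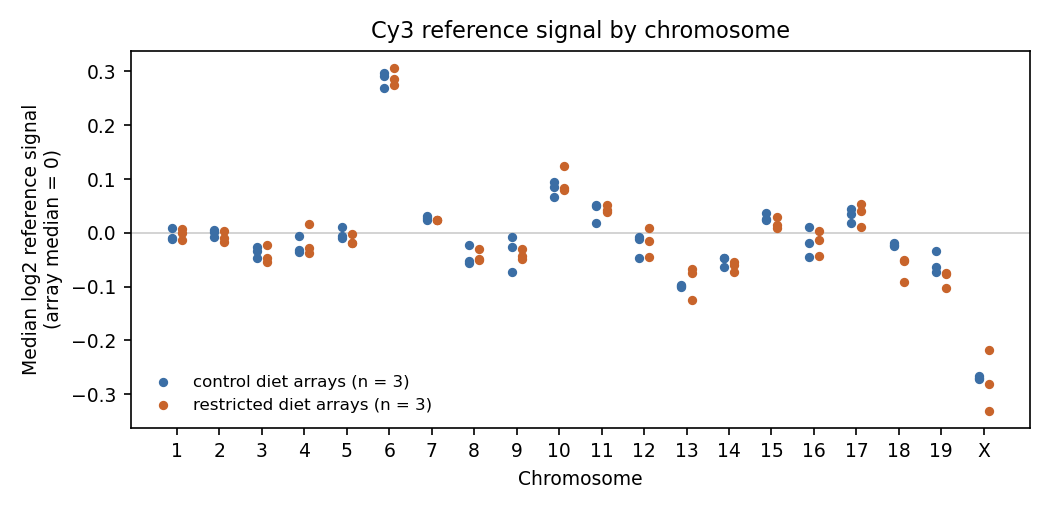
Median log2 Cy3 reference signal of the regions of each chromosome, relative to the array median (y axis), by chromosome (x axis), 1 point per array for 3 control (blue) and 3 restricted (orange) arrays. Chromosome 6 lies between 0.27 and 0.31 on all 6 arrays, and the X chromosome between -0.33 and -0.22.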

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

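Comparisons of slopes, fits and correlations by background set, counts of shared probes and the distance from the control arrays were chosen after the results were seen. The count over other splits of the arrays was planned. Of 16 groups of arrays tested for a value far from the rest, 4 had one, where chance gives about 1 in 20. The groups include those of the 4 named probes, which were chosen from these same arrays, so that rate does not hold for them.

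Restricted array 1 had a median intensity of never-detected probes of 159, while the nearest other restricted array was at 180. The same array stood apart for the 2 most reduced probes, with 7.20 for ILMN_2996479 (nearest 4.90) and 6.83 for ILMN_1231381 (nearest 5.25). Control array 6 stood apart for ILMN_2885990, with a log2 intensity of 6.21 (nearest control array 5.73).

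Of 100 splits of the 13 arrays, 1 gave as many as the 2271 expression changes between the diets, the real one, and the highest other gave 1. A random division of the arrays is thus argued against. Each other split put 1 to 4 of restricted arrays 2 to 6 in its group of 6, so none kept these 5 together. The splits therefore cannot tell diet from another grouping that holds those 5 arrays together. Array sets that were processed apart stay open as a candidate explanation of many changes. Of the 10632 never-detected probes, 1421 (13.4%) changed between the 8 and 5 arrays of the background sets and 567 (5.33%) between the diets. Across these probes restricted array 1 correlated at 0.04 with the control arrays and -0.26 with the other 5 restricted arrays. These values go with array sets. They do not settle the cause, since the sets were defined on these same probes and differ from the diets by restricted array 1 alone. Held out, restricted array 1 followed the changes of the other restricted arrays with a slope of 0.126, against 0.741 to 1.03 for each of those and -0.01 to 0.14 for held-out control arrays. Principal component 1 had already placed that array with the controls, and an unusual tumour on it would give the same slope. A control tumour like those on the 7 control arrays is argued against under the label of restricted array 1. The root mean square log2 distance of that array from the control mean was 0.572. This lies above the highest control array, at 0.425, by more than the controls' SD of 0.05. It lies inside the range of the other 5 restricted arrays, 0.523 to 0.640. An unusual control tumour stays open, because the distance has no direction. The slope of 0.126 lay inside the range of the held-out control arrays. The diet itself stays open too, since diet and array set cannot be told apart on the other 5 restricted arrays; the 82 probes shared between the calls with the background set as a block and the calls without restricted array 1, where independent lists would share 86.5, decide nothing, because both fits use the same controls and 1 array carries the former.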

How the results depend on the processing

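The background set as a block and all alternatives for the H3K4me3 gene lists were chosen after the data were seen; the other alternatives were planned. The number of changed expression probes stayed within 1.5 times 2271 in 17 of 22 alternatives. It was 6055 with array medians, 1079 with mouse number as a block (which also takes out control replicate 7, without a partner; leaving that array out alone gave 1688), 3951 with array weights and 305 with the background set as a block. Leaving out each mouse gave 1441 (without restricted replicate 2) to 3399 (without restricted replicate 1, which had a weight of 0.22). The cause was not tested. The 4 named probes kept their direction in 84 of 84 values and lost the call in 25. H3K4me3 gave 0 changed regions with limma in 18 of 18 alternatives, with 7 to 2622 regions or probes at an unadjusted p under 0.05, the lowest for regions with a mean log2 ratio of at least 1 and the highest for single probes. All 99 values of the named regions kept their direction and none passed the threshold, but sizes moved. Normexp gave 0.91 at Brms1l, 1.09 at Ranbp2, -0.95 at Wdr5 and -1.01 at Tex9, and medians over probes gave 0.31 at Snx11. The named probes and regions were chosen from these same arrays, so a kept direction was likely beforehand. The number of gene lists past camera was 1 in place of 0 with normexp (pigment cell genes, adjusted p = 0.0317), and 0 to 1 with each mouse left out, but 0 under each of these with an estimated correlation (smallest adjusted p = 0.694). The pigment cell genes' adjusted p ranged from 0.0305 to 0.928 over alternatives and that of the macrophage markers from 0.0185 to 0.685. Of 308 values of list levels, 297 moved by less than the spread. The difference in array enrichment was -0.0100 (exact permutation p = 1.00) with the SD of the log2 ratios in place of 0.08; the cause was not tested. Signal over background may limit H3K4me3, since 85.1% of probes were well above background in the reference channel on all 6 arrays. With a filter on that signal limma called 0 regions changed, and 329 had an unadjusted p under 0.05. Not run, for want of gene or BeadChip names, were the gene lists on expression, means over the probes of a gene, the correlations of the 2 assays and the BeadChip as a block.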

Other observations

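The gene families and the tests of chromosome 6 in this part were chosen after the results were seen; the splits of the ChIP-chip arrays were planned. H3K4me3 was high at several large gene families whose members lay mostly outside the fixed lists. The 75 ribosomal protein genes had a median log2 ratio of 0.74, above all of 10000 random matched lists, with Rps9 at 2.15 ± 0.50 (SD over the 6 arrays), Rps27a at 2.01 ± 0.59 and Rpl31 at 1.96 ± 0.52. The 67 mitochondrial ribosomal protein genes stood at 0.55, above all their random lists, with Mrpl1 at 1.79 and Mrpl24 at 1.61. The 50 spliceosome and RNA processing genes stood at 0.43 and the 30 proteasome subunit genes at 0.43 (percentile 99.7), with Psmd12 at 1.17 ± 0.44 and Psma3 at 1.09 ± 0.63. With the median over a region's probes these 4 families stood lower, at 0.43, 0.34, 0.19 and 0.24 in the same order, each still above its random median; the lowest percentile of the proteasome genes over 10 alternatives was 96.6, without restricted tumour 2. The 226 zinc finger protein genes were less clear, at 0.22 (percentile 99.2) and above their random median on 4 of 6 arrays, with 0.14 (percentile 92.2) without restricted tumour 3 and 0.09 with the median over probes. A log2 ratio of at least 1 on every array was found at 59 regions, among them Cflar, an inhibitor of caspase 8, at 2.61 ± 0.91, Qk, an RNA-binding protein gene, at 2.57 ± 0.72, Emc4 at 2.55 ± 0.33 and Heatr1 at 2.36 ± 0.85.

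Several other gene families had low medians. The 38 Hox genes, which pattern the body axis, had a median log2 ratio of -0.36, below all their random lists, with Hoxa2 at -1.12 ± 0.66 and Hoxc6 at -1.11 ± 0.34, although Hoxa10 was at 1.22 ± 1.03. The 119 genes of other developmental regulator families stood at -0.23, also below all their random lists, with Pax1 at -1.29 ± 0.30 and Pax8 at -1.29 ± 0.32. Sox6 at 1.10 ± 0.29 and Pax3, a regulator of the melanocyte lineage, at 0.84 ± 0.81 lay at the other end. The 78 potassium channel and glutamate receptor genes stood at -0.16, with Gria3 at -1.42 and Kcnj8 at -1.15. The sizes of these 3 medians depended on the processing: with normexp they were -0.07, -0.05 and -0.03, and with the median over probes -0.15, -0.10 and -0.09, below all random lists in each case. The 11 histone genes stood at -0.63, but at -0.08 with normexp and -0.41 without control tumour 3. Their medians per array were -0.98 ± 0.47 in control and -0.55 ± 0.99 in restricted tumours (SD, n = 3 each), with 1 of 6 arrays above the random median. The median of 4 olfactory and vomeronasal receptor genes was -0.30.

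The reference signal of chromosome 6 was 0.288 above that of all regions, against at most 0.09 for another autosome. Extra copies of chromosome 6 in the reference DNA are a candidate explanation: its lowest of 10 windows of 15 Mb had a median of 0.0955, and 0 of the 18 other autosomes had all windows above 0. The X chromosome stood at -0.27 on the same scale; its copy number in the reference is not known, since the labels leave open whether the DNA came from tumour or host. Brighter probes on chromosome 6 stay open, and the 2 explanations cannot be told apart here, because all 6 arrays carry the same reference and no DNA without such a gain was hybridized. No biological explanation by diet was tested, since the reference pools control-diet mice.

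For H3K4me3, all 10 splits of the 6 ChIP-chip arrays gave 0 changed regions, the real split and the highest other alike, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 373 regions and the others 378 to 1327. Mouse numbers did not pair the expression arrays of the diets: 1 of 6 restricted arrays correlated best with the control array of its own number, with r from -0.50 to 0.26 across probes. For H3K4me3 this held for 1 of 3, with r from -0.20 to 0.09 across regions.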
